A study of Homo sapiens with 34 samples.

How the data were processed

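RNA from the whole blood of 34 patients with sepsis was measured on Affymetrix arrays, 1 array per patient. The sample titles name 13 of them as patients with acute lung injury (ALI) and 21 as patients with sepsis. The groups are called ALI with sepsis and sepsis alone here. The deposited table holds 22277 probe sets. Total RNA was labelled with biotin, per the labels.

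The deposited values are log2 probe set summaries. They were made with GCRMA, per the submitters' processing notes. GCRMA subtracts a background predicted from each probe's sequence and summarises the probes of a set. Its version and settings are not given in the sources used here. The background step compresses dim probe sets into a narrow band, so a fold change that involves values in that band is not reliable. The array medians ran from 2.88 to 3.17 on the log2 scale and the 75th percentiles from 6.04 to 7.24. Neither was normalized again in the main analysis.

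Probe sets were named through the platform annotation, and symbols were updated through gene IDs to the GRCh38.p14 gene table. Of all probe sets, 19070 had 1 gene symbol, 1043 had several and 2164 had no gene listed in that table. For 19058 of those with 1 symbol the gene ID matched. Probe sets with several symbols or none were tested but are not named here. The arrays carry no genome coordinates and none are given.

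The 62 control probe sets were left out, as were 52 probe sets of XIST and Y-linked genes, which would track the sex of a person. Probe sets were kept when their log2 value exceeded 4 on at least 10 of the 34 arrays, counted without regard to group. This left 8762 probe sets, 39.3% of the array, of which 1019 had no single gene. They covered 5614 named genes.

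Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with all 34 arrays and no covariate, 2-sided. P-values were adjusted by the Benjamini-Hochberg method over the probe sets kept, with a threshold of 0.05. Differences are given as ALI with sepsis minus sepsis alone. The replicates are different patients, so the spread between arrays holds biological as well as technical variation. The number of arrays limits the precision.

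Before the data were examined, 25 gene lists of blood cell markers and pathways were fixed, with 1 probe set per gene, the kept one with the highest mean over all arrays. The eosinophil and basophil list had fewer than 5 kept genes and was not tested, which left 24. Lists were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated for each list, and with fry. Camera asks whether a list's genes shift relative to the other genes. Fry asks whether they move, on balance, one way. The means of the 10 blood cell lists, the first 5 principal components and the RNA integrity measure were compared with 2-sided permutation tests of 100000 resamples. RNA integrity was taken as the log2 signal of the 3' minus the 5' control probe sets of beta-actin and GAPDH, which rises as RNA degrades.

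The rule for named genes was also fixed beforehand. The 12 genes higher and the 12 genes lower with the largest change among those past the threshold were to be named, filled up by the smallest p-values where fewer passed. Within each list, the members past the threshold over the list alone, or otherwise the 2 with the smallest p, were to be given.

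The analysis was tested on simulated data. In 10 runs the real residuals were shuffled over the arrays and 200 of the 8762 probe sets were changed by known amounts. A 1.41-fold change was called in 15.2% of cases, a 2-fold change in 55.6%, a 2.83-fold change in 80.6% and a 4-fold change in 94%. Every call had the right direction, and 4.5 unchanged probe sets were called per run on average. These percentages apply to 200 changes at once. The Benjamini-Hochberg threshold is stricter where fewer probe sets change, so a lone change of the same size would be called less often.

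The patient numbers in the titles run from 1 in both groups. They name different people, so the main fit has no replicate block. Alternatives covered the filter, the normalization, the variance model, array weights, a rank-sum test, covariates, the replicate block and leaving out each array in turn. Scan dates and clinical measures were not used here. No individual array is named. Figures were drawn with matplotlib 3.10.9.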

Results

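Whole-blood gene expression was measured once in each of 34 patients with sepsis, 13 of whom also had acute lung injury (ALI), the sudden inflammatory failure of gas exchange that can follow sepsis. The comparison asked which blood transcripts distinguish patients who have ALI from those with sepsis alone. The technical measures of the groups were close. On average 38.4% ± 0.685 (SD, n = 13) of probe sets lay above the log2 floor of 4 in ALI with sepsis and 38.4% ± 0.559 (SD, n = 21) in sepsis alone. The 3' to 5' signal difference of the beta-actin and GAPDH controls, a sign of RNA degradation, was 1.33 ± 0.635 and 1.22 ± 0.499 on the log2 scale (permutation p = 0.607). Over the probe sets tested, pairs of arrays correlated between 0.588 and 0.969, with a median of 0.892, and no pair was close enough to be 1 array deposited in duplicate. The median correlation was 0.892 between ALI arrays, 0.889 between sepsis-alone arrays and 0.894 across the groups. The lowest median correlations to the others, 0.754 and 0.816, belonged to a pair of sepsis-alone arrays. The next lowest was 0.837, so only the first stood clearly apart.

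No gene separated ALI with sepsis from sepsis alone once the number of tests was taken into account. Of 8762 probe sets, 0 passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.999. At an unadjusted p under 0.05 there were 150 probe sets, 77 higher and 73 lower in ALI with sepsis, where 438 would be expected by chance alone. A rank-sum test also called 0 after adjustment, with 148 at an unadjusted p under 0.05. The median absolute difference was 0.14 on the log2 scale against a median standard error of 0.258. The 95% interval of the difference lay within 2-fold in either direction for 6732 probe sets, or 76.8%, and within 1.5-fold for 3327, or 38%.

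The genes named as lower in ALI with sepsis are those with the smallest p-values in that direction. None of them passed the adjusted threshold, all having an adjusted p of 0.999 in limma. CDKN1A, which encodes the cell cycle inhibitor p21, had the smallest p of all named genes. It stood at 7.43 ± 0.962 (SD, n = 13) in ALI with sepsis and 8.75 ± 0.885 (SD, n = 21) in sepsis alone, a log2 difference of -1.32 (SE 0.315, unadjusted limma p = 0.000187). In 12 of the 13 ALI arrays CDKN1A lay below the sepsis-alone median. CDKN1C, which encodes the related inhibitor p57, differed by -1.64 (SE 0.521), but it exceeded the floor on only 1 ALI array and on 11 sepsis-alone arrays. The small GTPase gene RHOB differed by -0.80 (SE 0.274), ARF3, a GTPase of membrane traffic, by -0.42 (SE 0.142; -0.19 and -0.22 on its other probe sets), and CDC42EP2, an effector of the GTPase CDC42, by -0.78 (SE 0.263). CDC42EP2 was below the sepsis-alone median in all 13 ALI arrays, and its other probe set differed by -0.57. The differences were -0.996 for TM9SF4, above the floor on 8 ALI arrays and 20 sepsis-alone arrays, -0.25 for its other, brighter probe set, -0.39 for the phosphatase inhibitor gene PPP1R11 and -1.46 for the butyrophilin-like gene BTNL8.

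The other genes named as lower were TREM1, ICAM2, HLA-DRA and HLA-DQB1. TREM1, a receptor on neutrophils and monocytes that amplifies inflammatory signals, averaged 9.71 ± 1.46 (SD, n = 13) in ALI with sepsis and 10.8 ± 1.01 (SD, n = 21) in sepsis alone. The TREM1 difference was -1.09 (SE 0.411). The adhesion molecule gene ICAM2 differed by -0.86 (SE 0.328), and by -0.73 on its other probe set. HLA-DRA, the alpha chain of the antigen-presenting molecule HLA-DR, differed by -0.86 (SE 0.332), below the sepsis-alone median in 12 of 13 ALI arrays. HLA-DQB1 differed by -0.87 (SE 0.311), and its other 5 probe sets had differences of the same sign, from -0.24 to -1.50. The gene is highly polymorphic, and its probe sets were designed on reference sequences.

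The genes higher in ALI with sepsis were of mixed function, and again none passed (adjusted p = 0.999 for each in limma). NQO2, a quinone reductase, had the smallest p in this direction, at 11.7 ± 0.898 (SD, n = 13) against 10.8 ± 0.706 (SD, n = 21), a log2 difference of 0.91 (SE 0.272). NQO2 exceeded the sepsis-alone median in 11 of the 13 ALI arrays. RAB27A, a GTPase needed for the release of secretory granules, differed by 0.66 (SE 0.247), and by 0.20 to 0.63 on its other 3 probe sets. The lipid enzyme genes PNPLA2, a triglyceride lipase, and FAR2, a fatty acyl-CoA reductase, differed by 0.48 (SE 0.154; 0.35 on its other probe set) and 0.91 (SE 0.351). HEXIM1, an inhibitor of transcription elongation, differed by 0.51 (SE 0.179; 0.24 on its other, brighter probe set), and MUS81, a DNA repair endonuclease, by 0.50 (SE 0.183). The differences were 0.77 for the tetraspanin gene TSPAN2, 0.79 for ITGB1BP1, 0.79 for SLFN12, 0.48 for ASB1 and 0.45 for SPSB3. The other probe sets of ASB1 and SPSB3 differed by 0.44 and 0.28. Some of these were dim. UPB1, at 1.07 (SE 0.388), exceeded the floor on 8 ALI arrays and 6 sepsis-alone arrays, TSPAN2 on 10 and 9, and SLFN12 on 10 and 10.

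**Figure D1:**
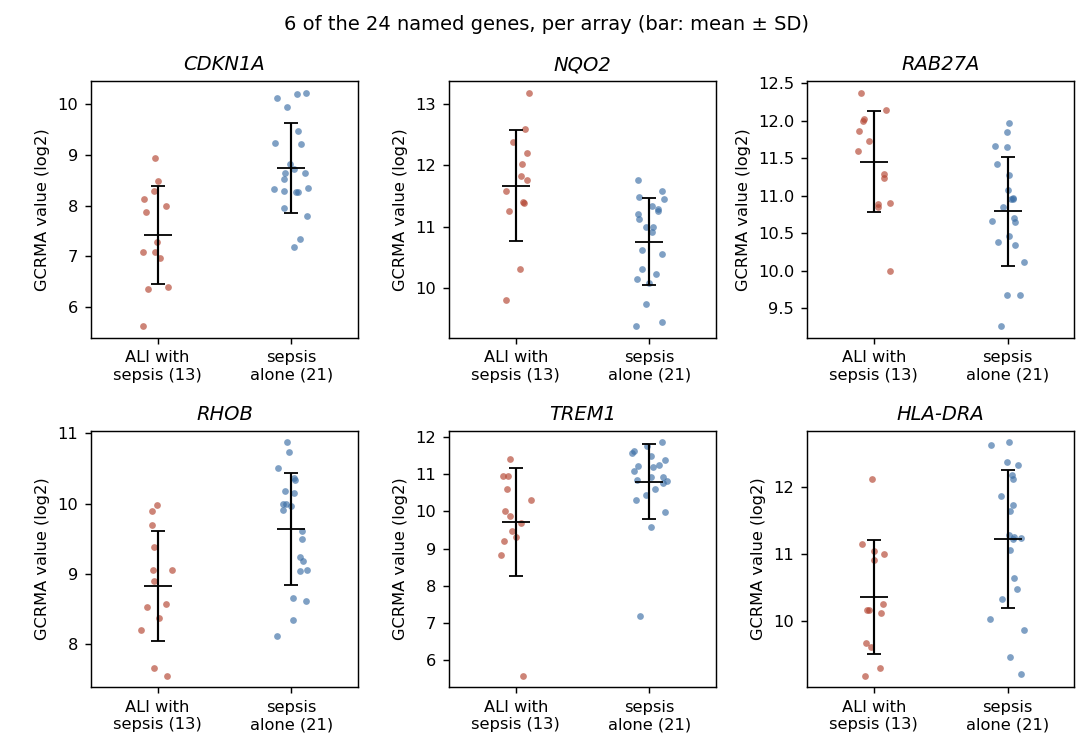
GCRMA values (log2, vertical axes with different ranges that do not start at 0) of 6 of the 24 named genes, picked for display after their values were seen; each point is 1 array, with 13 in ALI with sepsis and 21 in sepsis alone, and bars give the mean and SD. CDKN1A has the widest gap relative to its spread, at 7.43 against 8.75, and the groups overlap for every gene shown.

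Gene lists fixed in advance gave a more one-sided picture, but it rested on how the correlation between genes was treated. Counts of a list's genes cover only those kept for testing. With the preset correlation, camera called 6 of the 24 lists, all lower in ALI with sepsis: heat shock and endoplasmic reticulum (ER) stress, platelets, HLA class II, plasma cells, monocytes and the NF-kB inflammatory response. With the correlation estimated from these arrays, which ranged from 0.254 to 0.657 in those lists, none was called, and the smallest adjusted p = 0.403 with an estimated correlation. Fry called 0 lists, with an adjusted p of 0.982 for each of them. No list had a member past the threshold, whether adjusted over all genes or adjusted over the list alone, where the smallest adjusted p was 0.164.

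Of the 12 HLA class II genes on the array, which present antigen to helper T cells, 9 were kept for testing. All 9 had negative differences, with a median of -0.65 on the log2 scale (camera adjusted p = 7.76e-07, and adjusted p = 0.403 with an estimated correlation). At 1 probe set per gene, HLA-DRA differed by -0.75 (SE 0.326) and CD74, the invariant chain of class II molecules, by -0.65 (SE 0.298). Of the 24 heat shock and ER stress genes, 21 had negative differences, with a median of -0.37 (camera adjusted p = 1.5e-07; adjusted p = 0.403 with an estimated correlation). HSPA5, the main ER chaperone, stood at 10.2 ± 0.577 (SD, n = 13) and 10.8 ± 0.731 (SD, n = 21), a difference of -0.56, and the small heat shock protein gene HSPB1 differed by -0.63. Of the 22 platelet genes, 21 had negative differences, with a median of -0.44 (camera adjusted p = 5.06e-07; adjusted p = 0.791 with an estimated correlation). F13A1, coagulation factor XIII, differed by -0.85 (SE 0.408) and CLU, clusterin, by -0.59 (SE 0.306), while the abundant platelet chemokine genes PF4 and PPBP differed by -0.17 and less than 0.01.

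All 10 plasma cell genes had negative differences, with a median of -0.36 (camera adjusted p = 0.00351; adjusted p = 0.821 with an estimated correlation). XBP1, a transcription factor of secretory cells that the heat shock and ER stress list also holds, differed by -0.73 and MZB1 by -1.23. The mean of the plasma cell list was not lower in the typical ALI array, with group medians of 7.97 in ALI with sepsis and 7.89 in sepsis alone. A few sepsis-alone arrays lay far above the rest, at 10.8, 11.3 and 12.0, while the highest ALI array was at 8.63. Of 18 monocyte genes, 13 had negative differences, with a median of -0.28 (camera adjusted p = 0.0151; adjusted p = 0.922 with an estimated correlation). The examples were TNFRSF1B at -0.35 and CD86 at -0.52. Of 14 NF-kB inflammatory genes, 11 had negative differences, with a median of -0.22 (camera adjusted p = 0.0358; adjusted p = 0.922 with an estimated correlation). IL1B, the cytokine interleukin-1 beta, differed by -0.71 (SE 0.429) and PLAUR, the urokinase receptor, by -0.44 (SE 0.275). With 1 array left out at a time, the monocyte list stayed called in 28 of 34 fits and the NF-kB list in 24 of 34, with adjusted p-values of up to 0.196 and 0.495. The plasma cell list stayed called in 33 of 34, with an adjusted p of up to 0.0579.

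**Figure D2:**
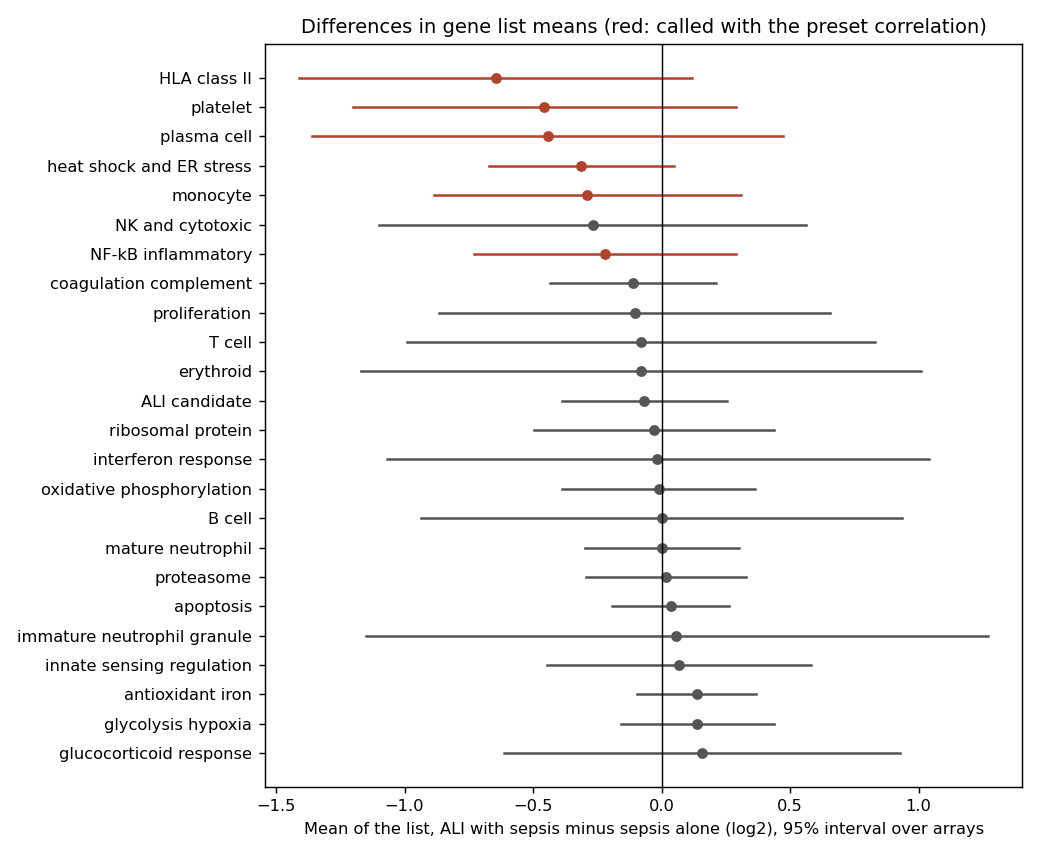
Difference between the groups in the mean of each of 24 gene lists (horizontal axis, log2, ALI with sepsis minus sepsis alone); points are differences, lines are 95% intervals from the spread between the 34 arrays, and red marks the 6 lists called with the preset correlation. Every interval includes 0, the HLA class II one running from -1.41 to 0.118.

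The remaining 18 lists were not called by any of these tests (smallest camera adjusted p = 0.296). Among lists of leukocyte genes, CD4 differed by -0.94 (SE 0.441) and CD27 by -0.46 in the T cell list, and CST7 by 0.63 and the perforin gene PRF1 by -0.77 in the natural killer (NK) and cytotoxic list, where 9 of 13 differences were negative. In the B cell list TCL1A differed by 0.47 and BANK1 by -0.22. Among neutrophil genes, MNDA differed by 0.26 (SE 0.111) and VNN2 by 0.37 in the mature list, and PGLYRP1 by 0.41 and MS4A3 by 0.81 (SE 0.833) in the immature granule list. In the erythroid list, where 17 of 26 differences were negative, ERMAP differed by 0.38 and GATA1 by 0.22.

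Pathways linked to sepsis or lung injury showed similarly small values. Of the 37 listed genes on the array that association studies have linked to ALI, 19 were kept for testing. These 19 had 10 positive and 9 negative differences. Their smallest p-values belonged to HMOX1, heme oxygenase 1, at -0.72 (SE 0.373), and THBD, thrombomodulin, at -0.83 (SE 0.542). In the antioxidant and iron list the glutathione reductase gene GSR differed by 0.71 (SE 0.366), beside HMOX1. Of the 28 interferon-response genes 14 had positive and 14 negative differences, IRF9 being at -0.28 and IFITM3 at -0.11. In innate sensing TREM1 was joined by IL1R1 at 0.81, and in the glucocorticoid response KLF9 differed by 0.62 and IL1R2 by 0.65. In coagulation and complement the examples were F13A1 and PLAUR, in glycolysis and hypoxia CA4 at 0.46 and PFKFB4 at 0.17, and in apoptosis BAD at 0.17 and CASP8 at 0.23. Among genes of basic cell machinery, values were -0.23 for NDUFC1 and -0.34 for NDUFA9 in oxidative phosphorylation, 0.16 for RPL27A and -0.16 for RPL8 among ribosomal proteins, 0.28 for PSMD6 and -0.29 for PSMB2 in the proteasome, and -0.30 for both MCM6 and MCM3 in proliferation.

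Medians and means of the lists that were not called lay close to 0 in most cases. The median was -0.39 in the NK and cytotoxic list, -0.11 in proliferation, 0.11 in the antioxidant and iron list, 0.10 in the glucocorticoid response, 0.09 in glycolysis and hypoxia and 0.08 in innate sensing. It was 0.06 or less in size for the other 12. Signs differed between median and mean in 5 lists. They were 0.05 and -0.08 for T cells, 0.00422 and -0.11 for coagulation and complement, 0.00585 and -0.07 for the ALI candidate genes, -0.02 and 0.04 for apoptosis, and -0.00168 and 0.06 for immature granules, and camera's direction was that of the mean in each. For B cells and the proteasome the median and mean were positive, but camera's direction, taken relative to the other genes, was lower. Their means, 0.00018 and 0.0174, lay below the median of 0.0252 over all genes, while the B cell median, 0.036, lay above it. The eosinophil and basophil list had only 4 kept genes and was not tested.

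Whole blood is a mixture of cells, so the marker lists of 10 blood cell types and states were compared as means per array. None passed the test (smallest adjusted p = 0.856, permutation tests over 10 lists). HLA class II genes averaged 9.04 ± 0.758 (SD, n = 13) in ALI with sepsis and 9.69 ± 1.21 (SD, n = 21) in sepsis alone, a difference of -0.64 with a 95% interval from -1.41 to 0.118 (permutation p = 0.0947). Platelet genes differed by -0.46 (interval -1.2 to 0.29), plasma cell genes by -0.44 (-1.36 to 0.473) and monocyte genes by -0.29 (-0.887 to 0.309). The plasma cell difference in means came from a few high sepsis-alone arrays, with an SD of 1.55 in sepsis alone and 0.571 in ALI with sepsis. Mature neutrophil genes averaged 12.2 in both groups, with an interval of the difference from -0.299 to 0.303. For the erythroid list, from -1.17 to 1.01, and the immature neutrophil granule list, from -1.15 to 1.27, the interval left a 2-fold difference open in both directions. A 2-fold decrease also remained open for the HLA class II, platelet, plasma cell and NK and cytotoxic lists, the last running from -1.1 to 0.563.

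**Figure D3:**
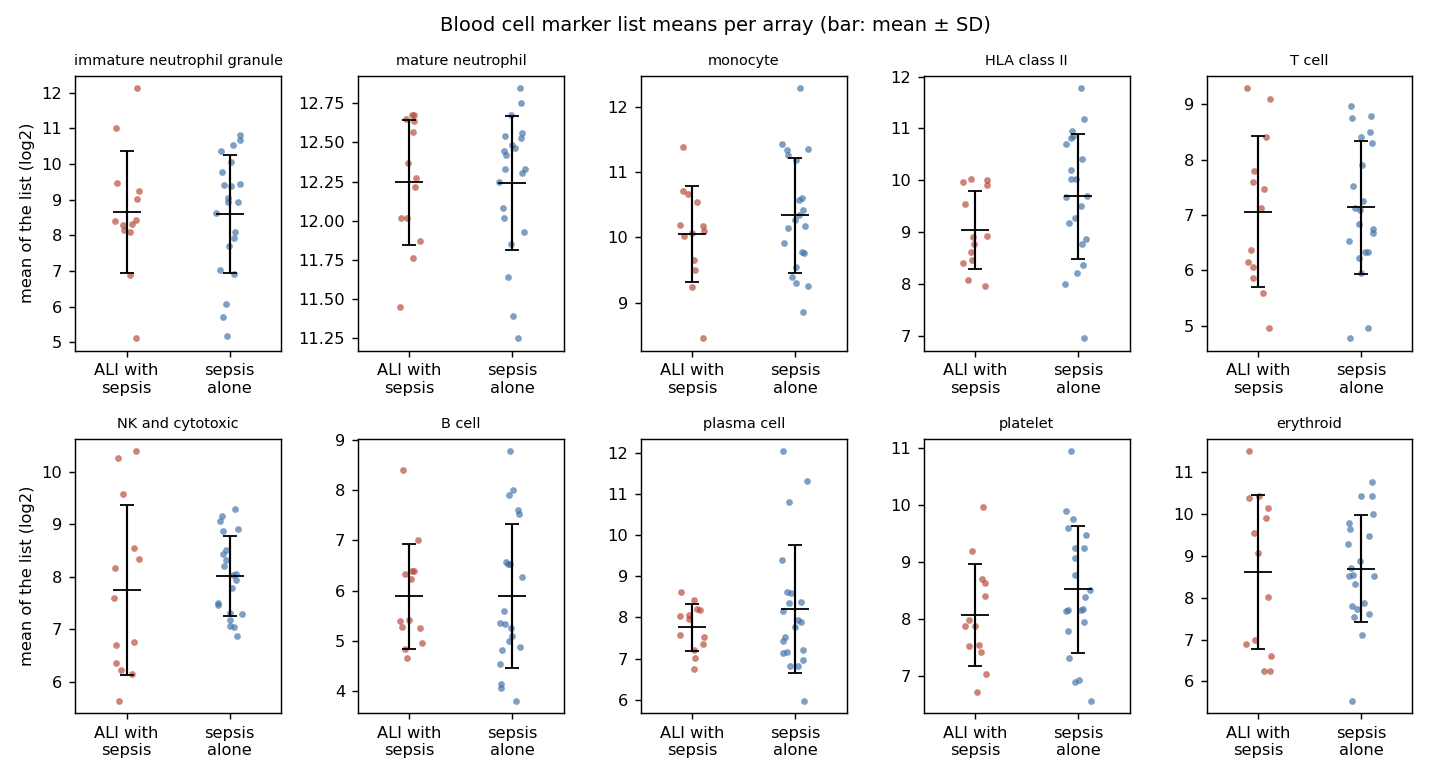
Means of 10 blood cell marker lists per array (vertical axes in log2, with different ranges that do not start at 0) in ALI with sepsis, 13 arrays, and sepsis alone, 21 arrays; each point is 1 array and bars give the mean and SD. The groups overlap in every list, and the NK and cytotoxic list has an SD of 1.61 in ALI with sepsis and 0.759 in sepsis alone.

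The groups were not told apart on the main axes of variation between patients either. The first 5 principal components held 66% of the variance, and the first alone 25.4%. Group means on the first component were 5.46 ± 37.3 (SD, n = 13) and -3.38 ± 47.9 (SD, n = 21). The permutation tests gave adjusted p-values of 0.828 or more for all 5 components.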

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

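The tests chosen after the result was seen were leaving out the 2 arrays least like the others, leaving out single arrays for the lists, the 5 principal components as covariates, and RNA integrity as a covariate for the lists. Dim probe sets near the background limit what fold changes can show. The count of 0 probe sets past the adjusted threshold was also 0 in the other settings run, at an adjusted p under 0.10 and with each array left out, with 2 exceptions of 1 probe set each. Array weights called a probe set with no listed gene (adjusted p = 0.0187), and the 5 components as covariates called IFFO1 (adjusted p = 0.0416, log2 difference 0.56). Both had an adjusted p of at least 0.999 without these settings, and they were singled out after their values were seen. The 150 probe sets at an unadjusted p under 0.05 became 231 with no filter, 99 with a mean of at least 6, 286 with array weights, 95 with 1 probe set per gene and 726 with the 5 components; the number of probe sets tested differs by construction with no filter, the mean of at least 6 and 1 probe set per gene, and otherwise the cause was not tested. Leaving out 1 array at a time gave 113 to 219.

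Of the lists, camera called 6, or 0 with the estimated correlation, 0 with fry and 10 with no filter, where oxidative phosphorylation, ribosomal, proliferation and coagulation lists were added, all lower. Leaving out 1 array gave 5 to 8. With the estimated correlation the adjusted p was 0.403 for HLA class II and heat shock, 0.791 for platelets, 0.821 for plasma cells and 0.922 for monocytes and NF-kB, and with fry it was 0.982 for all 6. The monocyte and NF-kB lists were also lost with a mean of at least 6 (0.0668 for both) and with RNA integrity as a covariate (0.0623 for both), where the ribosomal list was gained, as lower, and the monocyte list with the replicate block (0.0738). The cause was not tested. None of the 6 reversed. The 24 named genes kept their sign in all 320 values computed, and none passed the threshold. The kept signs are no separate support, since the genes were picked by p-value from the same arrays. Settings that change only the filter, the variance model or the test also leave a gene's difference unchanged. Marker list means reversed 4 times in 40, all near 0. Without the 2 arrays the mature neutrophil difference was -0.0462 and that of T cells 0.0440, and the B cell difference was -0.0436 after quantile normalization and -0.0671 with all members.

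The patient numbers shared by the groups do not pair people. Deviations of the 13 same-numbered pairs correlated between -0.356 and 0.561, above 0.1 in 3 pairs, and 1 matched best with its own number. The replicate block gave 0 probe sets and 183 at an unadjusted p under 0.05, and it called 5 lists.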

Other observations

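The tests on the spread between patients, on NK and cytotoxic genes, on RNA degradation as the whole cause of the HLA class II difference, on what the components follow and on splits with component covariates were chosen after the result was seen.

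The means of most gene lists varied more between patients than the means of random lists. The mean of the immature neutrophil granule list, led by MMP8, DEFA4 and ELANE, ranged over 7.01 log2 units across the 34 arrays (SD 1.66), beyond all 10000 random lists of the same size and expression. The erythroid list, led by FECH and SELENBP1, had an SD of 1.5, and the interferon-response list, led by IFI27 and IFIT1, an SD of 1.45. The ribosomal and oxidative phosphorylation lists, with SDs of 0.639 and 0.514, were also beyond all 10000 random lists. By contrast the means of the apoptosis and the antioxidant and iron lists had SDs of 0.313 and 0.326, at percentiles 54.9 and 73.4 of random lists. A list mean keeps the variation that its genes share and averages out the rest. The random lists therefore cannot separate wide variation between patients from genes that move together, and no conclusion on the width is drawn from them.

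The first 3 components were set against the list means, across 34 arrays and 72 relations tested. The immature granule and interferon lists, which spread widely, passed the test on none of them (adjusted p of r at least 0.103 and 0.619). The first component rose with the ALI candidate list (r = 0.874, rho = 0.831, permutation p = 1e-05 for both, the smallest they can give, adjusted p = 0.00012 for both; r = 0.789 without the 2 farthest arrays), with apoptosis genes despite their narrow spread (r = 0.82, permutation p = 1e-05, adjusted p = 0.00012; rho = 0.606, permutation p = 0.00021, adjusted p = 0.00126; r = 0.653 without them) and with innate sensing (r = 0.816, rho = 0.742, permutation p = 1e-05 for both, adjusted p = 0.00012; r = 0.697 without them). The second fell with HLA class II (r = -0.839, rho = -0.842, permutation p = 1e-05 for both, adjusted p = 0.00012; r = -0.796) and with T cells (r = -0.709, rho = -0.723, permutation p = 1e-05 for both, adjusted p = 0.00012; r = -0.713). The erythroid list fell with the first (r = -0.546, permutation p = 0.0008, adjusted p = 0.00411; rho = -0.668, permutation p = 4e-05, adjusted p = 0.00032; r = -0.725) and rose with the third (r = 0.665, permutation p = 2e-05, adjusted p = 0.000206; rho = 0.711, permutation p = 1e-05, adjusted p = 0.00012; r = 0.698). The components are built from the same genes, so these relations describe the axes and are not independent evidence. The test of the groups on the first component gave a permutation p of 0.58.

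NK and cytotoxic genes may have a larger spread between patients in ALI with sepsis, but the call depends on the setting. The SD of the list mean was 1.61 (n = 13) against 0.759 (n = 21), a ratio of 2.12. In the other direction, the plasma cell list had a ratio of 0.369 (permutation adjusted p = 0.364). The NK and cytotoxic list alone of 24 passed the threshold (permutation adjusted p = 0.0307). Of its 13 genes, 11 had the larger SD in ALI with sepsis, but they make up the list mean and are not separate support. The call was lost after quantile normalization (ratio 1.92, adjusted p = 0.225) and kept in 26 of 34 fits that left out 1 array, with an adjusted p of 0.00456 to 0.124 and a ratio of 1.93 to 2.24. Without the 2 ALI arrays least like the others the ratio was 2.21 (adjusted p = 0.0473), which argues against those 2 as the cause. They were not picked by their values in this list. A few ALI arrays with extreme values in the list, which ran from 5.64 to 10.4, therefore stay open as a cause. RNA degradation is argued against by a ratio of 2.09 with the control difference removed (unadjusted p = 0.0011). The T cell list had a ratio of 1.13 (bootstrap interval 0.72 to 1.65) and the dimmer B cell list 0.728 (0.391 to 1.13). The NK ratio was 1.87 times that of T cells (bootstrap interval 1.19 to 2.88) and 2.91 times that of B cells (1.51 to 6.01). Removing the T cell list mean, however, left a ratio of 1.59 (permutation p = 0.149). These values point both ways, so a varying lymphocyte share stays open. A biological difference of the patients with ALI also stays open and was not tested.

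The shortage of small p-values, 150 where 5% of the probe sets would be 438, may come from strong axes of variation that both groups share. With the first 5 components as covariates the count rose to 726, which fits that reading. The study's grouping was not unusual in this respect: among 100 splits of the 34 arrays into 13 and 21, the real one included, 74 gave at least as many small p-values, with a median of 346 and a highest of 1860 among the others, which points to structure among the samples. The 726 cannot be taken as a signal of ALI, since 9 of 100 splits gave as many with the same covariates, the highest being 1110. For the adjusted threshold the comparison decides nothing, since all 100 splits must give at least the 0 found; the highest other gave 38.

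With the preset correlation 86 of 100 splits called at least 6 lists, so chance is not excluded for their number. All 99 other splits called lists, from 2 to 15 with a median of 9. The preset correlation thus called lists in random splits as readily as in the study's groups. Its calls alone are therefore no evidence of a shift with ALI. By the size of the mean difference, 9 of 100 splits were as large for HLA class II, 14 for heat shock and ER stress, 21 for platelets, 34 for NF-kB, 43 for monocytes and 44 for plasma cells, so chance is not excluded for any of them. For HLA class II, the list with the largest difference, a smaller share of monocytes and B cells cannot be excluded: with both marker means as covariates 67.8% of the difference of -0.64 remained, with a bootstrap interval from -58.9% to 242%. With RNA integrity as a covariate 104% remained (41.9% to 146%), which argues against degradation as the whole cause and leaves a part open. For heat shock and ER stress genes RNA degradation is argued against, with 103% of the difference kept (63.4% to 149%). The control difference was similar in the groups, at 1.33 and 1.22 (permutation p = 0.607). Both RNA integrity shares mostly restate this, and they cover only degradation that the beta-actin and GAPDH controls reflect. For heat shock and ER stress genes fewer plasma cells stay open at 72.4% (-32.9% to 132%). No effect of ALI itself on the HLA class II or the heat shock and ER stress list was told from chance.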
